A study of Mus musculus with 22 samples.

How the data were processed

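The series holds 22 RNA-seq libraries of regulatory T cells (Tregs) marked by Foxp3-YFP, each from 1000 cells sorted in 2 rounds from mouse visceral adipose tissue at ZT0, the start of the light phase. The mice were males of the Foxp3-Cre-YFP strain, and the labels call the cells Bmal1 WT or KO. Messenger RNA was primed with oligo(dT), amplified by PCR and made into libraries by tagmentation, and this kit does not mark the strand. The reads were pairs of 38 bases. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.7.3a and assigned to genes with featureCounts, whose version and strand setting are not given in the sources used here. The deposited table holds the resulting integer counts, with no scaling by the authors stated or seen. It lists 55011 gene symbols. Of these, 52936 (96.2%), carrying 99.4% of the counts, were found in the annotation used for positions and overlaps, GENCODE mouse release M21.

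Total counts ran from 1955940 to 3467019 in the 18 diet libraries and from 4814337 to 5990319 in the 4 transfer libraries, and 18898 to 23400 genes had at least 1 count. A gene with no count in a library could be present at up to 3 counts, which is 0.506 to 1.63 CPM (counts scaled to a common library total, here after TMM) depending on the library. Such floors cover counting error only, since PCR copies of 1 molecule are counted apart. No library was left out of the reported tests.

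Groups were taken from the labels alone: lean diet, 4 weeks and 16 weeks of high fat diet, each with 3 WT and 3 KO libraries, and adoptive transfer with 2 WT and 2 KO libraries. The comparisons, the tests, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Counts were scaled by TMM and tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with Benjamini-Hochberg (BH) adjustment and an adjusted p under 0.05 as the threshold. Adjusted p values for genes come from this test unless another is named. The 18 diet libraries were fitted together with a mean per group, and the 4 transfer libraries alone. The edgeR filter on low counts (minimum count 10) left 11698 genes in the diet libraries and 11715 in the transfer libraries. Comparisons were KO against WT within each diet, averaged over the 3 diets and after transfer, high fat against lean diet within each genotype, and the genotype by diet interactions. CPM values are TMM-scaled group means with the SD over libraries, and log2 fold changes carry their standard error. Where every library on a side of a comparison had no count, a fold was computed against 3 counts in each of them, as the mean of their CPM, and is given as a lower bound.

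Named genes followed a rule. Arntl and the clock list members came first. Then came up to 6 genes per direction with the greatest log2 fold change among those past the threshold, with CPM ranges that did not overlap and a mean of at least 5 CPM in a group. For the average over diets the fold had to go the same way in all 3 diets, and no range was asked of interactions. List members past the threshold were added, up to 6 per list by smallest p, and where fewer than 10 genes passed, the 5 smallest p in each direction. Predicted genes, Rik clones, pseudogenes and receptor segments were left out of the choice by fold or by smallest p. Genes named from outside the rule are given as chosen after their values were seen. Some genes that the rule would name are not reported here.

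The 28 gene lists covered clock genes driven by BMAL1-CLOCK, clock genes under REV-ERB and ROR control, core Treg identity, the adipose tissue Treg signature, resting and lymphoid tissue T cell genes, T helper effector genes, immediate early and TCR-induced genes, NF-kB targets and interferon-stimulated genes. They also covered cell cycle, apoptosis and p53 targets, heat shock, the unfolded protein response, oxidative stress, nuclear oxidative phosphorylation, mitochondrially encoded genes, glycolysis, fatty acid uptake and oxidation, and sterol and fatty acid synthesis. The last 9 held markers of other cells: B cells, macrophages, dendritic cells with class II genes, cytotoxic T and NK cells, endothelial, stromal, mesothelial and epithelial cells, adipocytes and red blood cells. Every listed symbol was in the table except in the oxidative phosphorylation list, where 54 of 66 were, the rest having newer symbols. Lists with enough measured members, 22 in the diet libraries and 23 in the transfer libraries, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, and BH adjusted within each comparison. Camera with an estimated correlation, fry and a replicate block were the alternatives. In the 11 comparisons camera called 57 list changes, of which 9 held with an estimated correlation. Fry tests whether the genes of a list move one way on balance, without comparing them with other genes.

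Alternatives, changed 1 at a time, were RLE scaling, no filter on low counts, a stricter filter (1 CPM and 20 counts), a robust edgeR fit, the DESeq2 1.42.0 Wald test, the replicate number as a block, other sets of libraries in the fit and leaving out each library in turn. After the data were seen, leaving out 3 libraries with high markers of other cells was added, and so was not counting calls near Arntl or near Ptprc. A count was taken as moved when it differed by more than 1.5 times. A named gene was taken as weaker or stronger when it lost or gained the threshold, and as reversed when its sign changed and either value passed. Replicate numbers were checked for pairing across groups. In none of the 8 pairs of groups did every same-numbered pair of libraries have a correlation of residuals over 0.1. Libraries were therefore not paired in the reported tests, though this check cannot exclude pairing.

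The tests were checked on simulated counts for the real genes and library sizes, with 67, 67 and 66 genes changed by 1.5, 2 and 3 times. For KO against WT on lean diet, over 11490 genes, 7.46%, 31.3% and 72.7% of the changed genes were called. For the average over diets (11492 genes) the shares were 50.7%, 71.6% and 87.9%, and for 16 weeks of high fat diet against lean in KO (11461 genes) 2.99%, 41.8% and 68.2%. For the interaction at 16 weeks (11507 genes) they were 0, 10.4% and 48.5%, and after transfer (11246 genes) 8.96%, 26.9% and 48.5%. False calls numbered 3, 0, 1, 5 and 2 in that order.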

Results

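Gene expression was measured by RNA-seq in 22 libraries of Foxp3-YFP+ Tregs from visceral adipose tissue of male mice, labelled Bmal1 WT or Bmal1 KO. BMAL1, encoded by Arntl, is the transcription factor that drives the circadian clock together with CLOCK or NPAS2. The lean diet and the 4 weeks of high fat diet groups were 18 weeks old, and the 16 weeks of high fat diet groups were 30 weeks old, after 14 weeks of lean diet. Each of these groups held 3 WT and 3 KO libraries. The transfer groups were sorted 9 weeks after adoptive transfer, with the mice 20 weeks old at sacrifice, and held 2 WT and 2 KO libraries. Total counts ran from 1955940 to 3467019 in the diet libraries and from 4814337 to 5990319 in the transfer libraries. Nothing in the labels says that replicates are separate animals, so p values measure only the spread between libraries.

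Treg identity was high in every group. Foxp3, the lineage factor of Tregs, had group means from 497 ± 29.8 CPM (SD, n = 3) in KO on lean diet to 617 ± 37.0 CPM (SD, n = 2) in transferred WT cells. Il2ra, the high affinity IL-2 receptor chain, ran from 369.6 ± 110 CPM in WT after 16 weeks of high fat diet to 1618 ± 259 CPM in transferred KO cells. Cd8a averaged 0 CPM in every group except transferred KO cells (0.17 CPM), and Lyz2, a myeloid gene, stayed between 0.44 and 1.86 CPM. Among markers of other cells, summed B cell markers ran from 143.95 ± 21.006 CPM in transferred WT cells to 1029 ± 265 CPM in KO after 16 weeks of high fat diet. Group means of the summed mesothelial and epithelial markers were 112 to 189 CPM and of red blood cell markers 0.56 to 4.08 CPM, and these were not tested as sets, nor were the endothelial, stromal and cytotoxic markers.

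Arntl itself had like counts in libraries labelled KO and WT. Its mean was 86.1 ± 15.1 CPM in KO and 70.8 ± 5.40 CPM in WT on lean diet (SD, n = 3 each). It was 88.5 ± 4.599 and 85.6 ± 20.9 CPM after 4 weeks of high fat diet, and 88.9 ± 4.88 and 71.3 ± 12.9 CPM after 16 weeks. After transfer it was 89.8 ± 0.48 CPM in KO and 84.5 ± 8.27 CPM in WT (n = 2 each). The average log2 fold change over the diets was 0.22 ± 0.10 (adjusted p = 0.652), with 0.29 on lean diet (0.781), 0.05 at 4 weeks (0.999), 0.32 at 16 weeks (0.628) and 0.09 after transfer (0.983). The labels do not give the deleted part of the gene, and a count over the whole gene cannot tell a transcript that lacks it, so Arntl checks nothing about the labels. In the mm10 annotation Arntl lies on chromosome 7 from 113207465 to 113314126, and the antisense Gm45355 overlaps it. Strand was not marked by the kit, so reads of overlapping genes on opposite strands are not separated here or for the other overlapping genes named.

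KO against WT on lean diet asks what the loss of Bmal1 does in unchallenged fat. Nr1d2 and Nr1d1, the REV-ERB repressors that BMAL1 drives, were nearly lost. Nr1d2 fell from 49.0 ± 4.49 CPM in WT to 1.41 ± 1.32 CPM in KO, 31.9-fold lower (log2 -5.00 ± 0.49, adjusted p = 2.32e-05). Nr1d1 fell from 37.6 ± 10.1 to 2.17 ± 2.00 CPM (log2 -3.98 ± 0.49, adjusted p = 0.000354), with Thra overlapping it on the opposite strand. Genes that REV-ERB represses rose. Cry1 went from 73.3 ± 9.11 to 183 ± 19.0 CPM (log2 1.32 ± 0.14, adjusted p = 7.73e-05). Npas2, which can replace CLOCK as the partner of BMAL1, went from 5.14 ± 4.67 to 55.5 ± 2.48 CPM (log2 3.46 ± 0.50, adjusted p = 0.00329).

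Of the 11 BMAL1-CLOCK driven clock genes, 0 rose and 2 fell on lean diet, or 1 (Cry2) and 4 (Ciart, Nr1d1, Nr1d2 and Per3) adjusted over the list alone. Their median log2 fold change was -0.41 (camera adjusted p = 4.96e-06, and 0.00456 with an estimated correlation). Of the 6 clock genes under REV-ERB and ROR control, 2 rose, also adjusted over the list alone, with a median of 0.73 (camera adjusted p = 1.7e-05, and adjusted p = 0.00963 with an estimated correlation). Outside the clock lists 1 gene passed: Zswim4, at 156 ± 26.1 CPM in KO and 70.8 ± 16.4 CPM in WT (log2 1.14 ± 0.21, adjusted p = 0.0462). The next genes did not pass, among them Furin, a protease that matures TGF-beta (log2 1.39, adjusted p = 0.0844), the early response factor Egr1 (1.30, 0.102) and Atp11b (-1.02, 0.162).

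Other lists on lean diet shifted together without a single member past the threshold over all genes. The immediate early and TCR-induced genes, which respond within minutes to hours of receptor signalling, had 0 of 25 past it and 11 that rose adjusted over the list alone. Their median log2 fold change was 0.49 (camera adjusted p = 2.09e-09, adjusted p = 0.14 with an estimated correlation). Summed heat shock genes, which also answer to handling, were 6917 ± 1810 CPM in KO and 5962 ± 64.0 CPM in WT, with lean KO library 1 apart at 9005 CPM. The adipose tissue Treg signature had 21 of 22 members with positive folds and 0 past the threshold, also adjusted over the list alone (median 0.39, camera adjusted p = 4.96e-06, adjusted p = 0.253 with an estimated correlation). Oxidative phosphorylation genes had 46 of 54 positive folds and 0 past the threshold either way (0.12, 4.52e-05, and adjusted p = 0.354 with an estimated correlation). Sterol and fatty acid synthesis genes had 0 of 26 past the threshold, and 3 (Hmgcs1, Msmo1 and Sqle) rose adjusted over the list alone (0.17, 0.00141, and adjusted p = 0.382 with an estimated correlation). Summed B cell markers were 368 ± 11.4 CPM in KO and 443 ± 99.3 CPM in WT. In all, edgeR called 5 genes, 3 higher and 2 lower in KO. The count was 11 without lean WT library 1, and Zswim4 lost its call without any 1 of the other 5 lean libraries (adjusted p from 0.0541 to 0.579, and from 9.6e-07 to 0.579 over all alternatives).

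After 4 weeks of high fat diet the clock genes Nr1d2, Nr1d1, Cry1 and Npas2 passed, as on lean diet. Nr1d2 was 1.87 ± 0.99 CPM in KO and 32.1 ± 7.10 CPM in WT (log2 -4.06 ± 0.46, adjusted p = 0.000227), and Nr1d1 was 2.79 ± 1.60 and 27.8 ± 4.78 CPM (log2 -3.28 ± 0.46, adjusted p = 0.00279). Cry1 rose to 227 ± 9.30 from 98.7 ± 10.8 CPM (log2 1.20 ± 0.14, adjusted p = 0.000227), and Npas2 to 60.8 ± 4.26 from 6.02 ± 3.52 CPM (log2 3.28 ± 0.48, adjusted p = 0.00341). Per3, a clock repressor, did not pass (log2 -1.63, adjusted p = 0.473). Furin was 427 ± 179 CPM in KO and 150.1 ± 22.5 CPM in WT (log2 1.505 ± 0.27, overlapped by Gm44851). The cytoskeletal linker Dst was 118 ± 18.3 and 61.7 ± 7.16 CPM (log2 0.93 ± 0.17, overlapped by A930005N03Rik and Gm26788). Art2b, a surface ADP-ribosyltransferase of T cells, was 15.9 ± 1.83 and 63.7 ± 19.8 CPM (log2 -2.001 ± 0.35). Each of these 3 genes had an adjusted p of 0.0269. Gm3617, which lies within Npas2 and was chosen after its values were seen, completed the 8 calls (log2 6.18, adjusted p = 0.0269).

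Of the 11 BMAL1-CLOCK driven genes 2 fell at 4 weeks, or 3 with 1 that rose adjusted over the list alone (median log2 fold change -0.26, camera adjusted p = 0.00652, adjusted p = 0.0506 with an estimated correlation). Of the 6 REV-ERB and ROR genes 2 rose both ways (0.59, 3.47e-06, and adjusted p = 0.00755 with an estimated correlation). Interferon-stimulated genes, the antiviral response set, had 23 of 25 negative folds and 0 past the threshold, also adjusted over the list alone (median -0.40, camera adjusted p = 6.28e-06, adjusted p = 0.59 with an estimated correlation). Likewise 0 members passed either way among the 22 adipose Treg genes (0.31, camera adjusted p = 0.0384), the 26 sterol genes (0.14, camera adjusted p = 0.0384) and the 6 dendritic cell and class II markers (-0.51, camera adjusted p = 0.045). In that order the adjusted p was 0.674, 0.674 and 0.366 with an estimated correlation. Summed B cell markers were 457 ± 66.9 CPM in KO and 618 ± 191 CPM in WT, cytotoxic T and NK markers 139 ± 50.2 and 243 ± 74.1 CPM, and macrophage markers 98.4 ± 9.93 and 130 ± 62.6 CPM. WT library 3 had the highest B cell (832 CPM), macrophage (201 CPM) and class II (179 CPM) sums of its group. Of the 8 genes called by edgeR, 5 were higher and 3 lower in KO. The count was 4 without WT library 1, WT library 3 or KO library 3 of this diet, and 5 without KO library 1 or 2. Art2b kept its call only without WT library 2, Dst only without KO library 1 and Furin only without KO library 2, with adjusted p values up to 0.256, 0.332 and 0.256 in the other leave-one-out fits. Over all alternatives these ran from 2.87e-12 to 0.256, from 0.000484 to 0.332 and from 8.87e-20 to 0.307.

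After 16 weeks of high fat diet Per3 passed the threshold over all genes, and fell from 21.8 ± 5.36 CPM in WT to 1.06 ± 0.59 CPM in KO (log2 -4.28 ± 0.47, adjusted p = 9.4e-05; interaction against lean diet, adjusted p = 0.314). Nr1d2 was 2.10 ± 1.27 CPM in KO and 33.7 ± 5.32 CPM in WT (log2 -4.00 ± 0.45, adjusted p = 9.4e-05). Nr1d1 was 1.34 ± 0.78 and 22.7 ± 8.07 CPM (log2 -4.05 ± 0.52, adjusted p = 0.000478) and Cry1 was 174 ± 27.7 and 73.3 ± 8.78 CPM (log2 1.24 ± 0.14, adjusted p = 9.4e-05). Npas2 was 15.8 ± 4.90 and 3.82 ± 1.17 CPM and did not pass (log2 2.04, adjusted p = 0.201). Ccr3, the eotaxin receptor, fell from 127 ± 49.9 to 30.9 ± 7.38 CPM (log2 -2.03 ± 0.30, adjusted p = 0.00368). Among genes that did not pass were Trim30d (log2 -5.32, adjusted p = 0.0715), the endothelial Cldn5 (5.67, 0.0994), the cell cycle factor E2f2 (1.03, 0.132) and Tspoap1 (1.14, 0.132).

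Of the 11 BMAL1-CLOCK driven genes 3 fell at 16 weeks, or 4 adjusted over the list alone (median log2 fold change -0.14, camera adjusted p = 0.000243, adjusted p = 0.0212 with an estimated correlation). Of the 6 REV-ERB and ROR genes 1 rose, or 2 with 1 that fell adjusted over the list alone (0.60, 0.0713, and adjusted p = 0.295 with an estimated correlation). All 27 cell cycle genes had positive folds in KO, with 0 past the threshold and 8 that rose adjusted over the list alone (median 0.79, camera adjusted p = 8.66e-13, adjusted p = 0.295 with an estimated correlation). The immediate early list had 0 of 25 past it, with 11 that fell and 1 that rose adjusted over the list alone (-0.44, 2.56e-06, and adjusted p = 0.295 with an estimated correlation). The adipose Treg list had 0 of 22 past it, with 7 that fell and 1 that rose adjusted over the list alone (-0.35, 0.00713, and adjusted p = 0.569 with an estimated correlation). Interferon-stimulated genes had 22 of 25 positive folds and 0 past the threshold either way (0.27, 0.0104, and adjusted p = 0.731 with an estimated correlation). The 4 B cell markers were all positive with 0 past the threshold either way (0.77, 0.0319, and adjusted p = 0.295 with an estimated correlation), their sum being 1029 ± 265 CPM in KO and 686.0 ± 283 CPM in WT. Summed cytotoxic T and NK markers were 132 ± 12.6 CPM in KO and 349.6 ± 293 CPM in WT, or 181 CPM without WT library 3 (687 CPM). Mesothelial and epithelial sums were lower in KO (112 ± 2.05 against 162 ± 90.8 CPM), and others higher: endothelial 179.9 ± 56.3 against 95.4 ± 60.6 CPM, adipocyte 53.5 ± 33.1 against 31.4 ± 7.04 CPM, dendritic cell and class II 168 ± 35.7 against 118 ± 33.4 CPM and stromal 87.8 ± 127 against 11.4 ± 5.68 CPM. Without KO library 1 the KO stromal and adipocyte means were 14.4 and 34.4 CPM, and without WT library 1 the WT endothelial mean was 60.58 CPM. The mesothelial and epithelial difference rests on WT library 2 (258 CPM), the other WT libraries having 78.2 and 149 CPM against 109 to 113 CPM in KO. The 5 calls were 1 higher and 4 lower gene. Without WT library 1 of this diet the count was 35, and without KO library 1 Ccr3 lost its call (adjusted p = 0.0767, and from 8.36e-27 to 0.413 over all alternatives).

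Averaged over the 3 diets, with 9 KO and 9 WT libraries, the same 5 clock genes led. The log2 fold changes were -4.35 ± 0.27 for Nr1d2 (adjusted p = 6.12e-09), -3.77 ± 0.28 for Nr1d1 (8.13e-08), -2.66 ± 0.25 for Per3 (2.4e-06), 1.25 ± 0.08 for Cry1 (8.93e-09) and 2.93 ± 0.29 for Npas2 (5.5e-06). Cry2, a clock repressor overlapped by D930015M05Rik, did not pass (0.60, 0.128). Furin rose from 132 ± 41.6 to 317 ± 178 CPM (log2 1.09 ± 0.15, adjusted p = 0.00108). The RhoGAP gene Stard8 rose from 1.12 ± 1.01 to 4.38 ± 1.59 CPM (3.06 ± 0.50, 0.00871). It had 0 counts in every WT library at 4 weeks, so the size of this average log2 fold change is uncertain. The hair keratin Krt83 went from 5.31 ± 3.68 to 13.4 ± 4.57 CPM (1.48 ± 0.27, 0.0138) and the receptor gene Lilr4b from 244 ± 51.2 to 374 ± 78.3 CPM (0.61 ± 0.12, 0.0342).

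Some genes of the Trim cluster on chromosome 7, which encode antiviral restriction factors of near-identical sequence, fell in the average. Trim12a (104299894 to 104315466) was 5.94 ± 11.8 CPM in KO and 58.3 ± 17.4 CPM in WT (log2 -5.18 ± 0.86, adjusted p = 0.00924). Every KO library at 16 weeks had 0 counts of it, so the size of this average log2 fold change is uncertain. Trim30d was 2.41 ± 3.56 and 20.8 ± 7.17 CPM (-3.37 ± 0.51, 0.00231) and Trim5 was 3.07 ± 5.13 and 19.9 ± 8.22 CPM (-3.02 ± 0.61, 0.04). Other copies, named after their values were seen, did not pass: Trim34b was higher in KO (8.36 ± 3.68 against 1.80 ± 2.48 CPM, adjusted p = 0.151), and Trim12c and Trim30a had log2 fold changes of 0.20 and -0.12. Reads of such copies can be split between them by the counting, so each single value is uncertain. Trim12a was at 0 in 7 of the 9 KO diet libraries and at 26.5 and 26.9 CPM in the others, against 35.3 to 79.9 CPM in the WT diet libraries. Art2b (log2 -1.52, adjusted p = 0.000544), Gm1966 (-2.26), Gm4759 (-0.64) and Trim34a (-1.24) also fell and lie within 20 Mb of Arntl; they were chosen after their values were seen, as were Gm3617 (3.80), Dhx40 (0.49), Eloa (0.47), Gps2 (-0.38), Lpar6 (0.45) and the non-coding Gm35082 near Arntl.

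In the average both clock lists were called. Of the 11 BMAL1-CLOCK driven genes 3 fell, or 5 with 2 that rose adjusted over the list alone (median log2 fold change -0.24, camera adjusted p = 7.93e-07, adjusted p = 0.0024 with an estimated correlation). Of the 6 REV-ERB and ROR genes 2 rose both ways (0.49, 6.96e-07, and adjusted p = 0.0024 with an estimated correlation). Cell cycle genes had 26 of 27 positive folds (0.30, camera adjusted p = 9.88e-07) and oxidative phosphorylation genes 45 of 54 (0.05, camera adjusted p = 0.0316). Both had 0 past the threshold, also adjusted over the list alone, and adjusted p = 0.761 with an estimated correlation. edgeR called 21 genes, 10 higher and 11 lower in KO. Of the 12 named genes that passed, 9 kept their call in all 18 leave-one-out fits. Trim5 lost it in 12 (adjusted p from 0.0501 to 0.136), Lilr4b in 10 (0.0541 to 0.114) and Krt83 without lean WT library 2 (0.0566), and over all alternatives their adjusted p values reached 0.284, 0.114 and 0.0633.

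**Figure D1:**
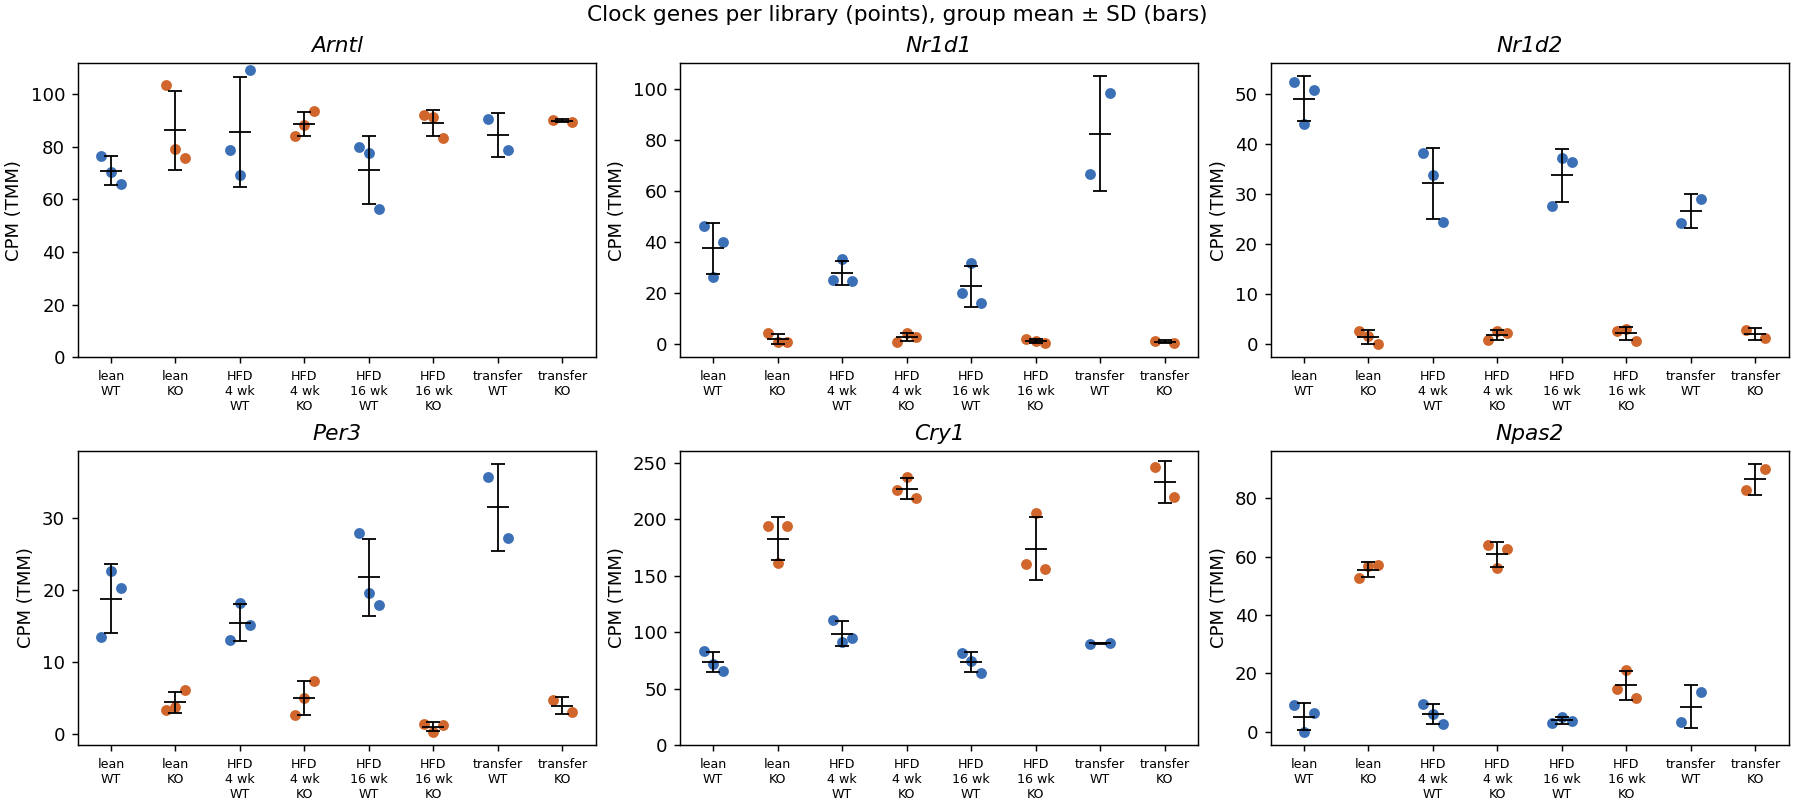
Clock genes in every library: the horizontal axis gives the 8 groups (lean diet, 4 and 16 weeks of high fat diet, transfer; WT blue, KO orange), the vertical axis TMM-scaled CPM, each point 1 library and the bars the group mean and SD. Arntl means lie between 70.8 and 89.8 CPM in all groups, while Nr1d1 and Nr1d2 are at most 2.79 CPM in each KO group mean, and Cry1 and Npas2 are higher in KO than in WT in every group.

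After adoptive transfer the same clock genes differed between KO and WT cells. Nr1d1 fell from 82.4 ± 22.3 CPM in WT to 1.05 ± 0.50 CPM in KO (SD, n = 2 each), 78.4-fold lower (log2 -6.29 ± 0.41, adjusted p = 0.000233). Nr1d2 was 2.01 ± 1.12 and 26.6 ± 3.46 CPM (log2 -3.73 ± 0.51, adjusted p = 0.0267) and Per3 was 3.97 ± 1.18 and 31.4 ± 6.02 CPM (log2 -2.98 ± 0.41, adjusted p = 0.0267). Cry1 rose to 233 ± 18.4 from 90.1 ± 0.52 CPM (log2 1.37 ± 0.14, adjusted p = 0.00462) and Npas2 to 86.5 ± 5.25 from 8.48 ± 7.33 CPM (log2 3.31 ± 0.47, adjusted p = 0.0327).

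A second set of genes after transfer lies on chromosome 1 within 10 Mb of Ptprc, which encodes CD45. Ctse, an endosomal protease, was 47.2 ± 13.7 CPM in KO and 419.8 ± 60.8 CPM in WT (log2 -3.16 ± 0.21, adjusted p = 0.000233). Gpr25, an orphan receptor, had 0 counts in both KO libraries and 48.4 ± 4.84 CPM in WT, at least 86.1-fold lower by 3 counts per library (adjusted p = 0.000488). Gm26781 overlaps both Gpr25 and Camsap2, which was 5.02 ± 0.30 and 39.6 ± 3.23 CPM (log2 -2.97 ± 0.33, adjusted p = 0.00729). The antiproliferative Btg2 was 1772 ± 375 and 4578 ± 512 CPM (log2 -1.37 ± 0.14, adjusted p = 0.00462). For Ctse and Gpr25 the WT transfer libraries were the ones apart from the diet groups, whose means were 29.2 to 55.1 CPM for Ctse and 0 to 1.22 CPM for Gpr25.

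Genes higher in KO than in WT after transfer included the kinase Pim1, at 1670.2 ± 2.698 CPM in KO and 482 ± 18.9 CPM in WT (log2 1.79 ± 0.09, adjusted p = 9.96e-05, overlapped by Gm26885). The non-classical class I gene H2-Q7 was 1458 ± 58.0 and 697 ± 9.10 CPM (1.07 ± 0.09, 0.00144). Its diet group means were 1315 to 1578 CPM, so the WT transfer group was the one apart. Pim1 (from 29490753) and H2-Q7 (from 35439155) both lie on chromosome 17, and the cause of these calls was not tested. The actin regulator Cap1 was 479.8 ± 13.9 and 227 ± 3.54 CPM (1.08 ± 0.11, 0.00462, overlapped by Ppt1) and the kinase Fes was 85.3 ± 11.3 and 32.4 ± 0.90 CPM (1.40 ± 0.21, 0.0417). Chosen after their values were seen were Furin (log2 1.05 ± 0.11, adjusted p = 0.00462), Cd40lg (-1.61, 0.00729) and Cpm (-1.85, 0.0417). No list was called by camera (smallest adjusted p = 0.0985). Of the 11 BMAL1-CLOCK driven genes 3 fell, or 5 with 2 that rose adjusted over the list alone, and of the 6 REV-ERB and ROR genes 2 rose, or 3 adjusted over the list alone. Both lists had a camera adjusted p of 0.0985 and adjusted p = 0.918 with an estimated correlation. The adipocyte markers, tested as a set only here, had a camera adjusted p of 0.408. Summed cytotoxic T and NK markers were 42.3 ± 5.75 CPM in KO and 94.8 ± 10.6 CPM in WT. edgeR called 20 genes, 10 in each direction. Of 13 named genes that passed, 8 kept their call in all 4 leave-one-out fits, in which a lone library is assumed to vary like the other group. Fes lost it in all 4 (adjusted p from 0.0598 to 0.287), Nr1d2 and Per3 without WT library 1, WT library 2 or KO library 2 (0.0711 to 0.142 and 0.0566 to 0.216). Camsap2 lost it without WT library 1 (0.0677) and Npas2 without KO library 2 (0.0735). Over all alternatives the highest adjusted p was 0.492 for Fes and as given here for the other genes.

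**Figure D2:**
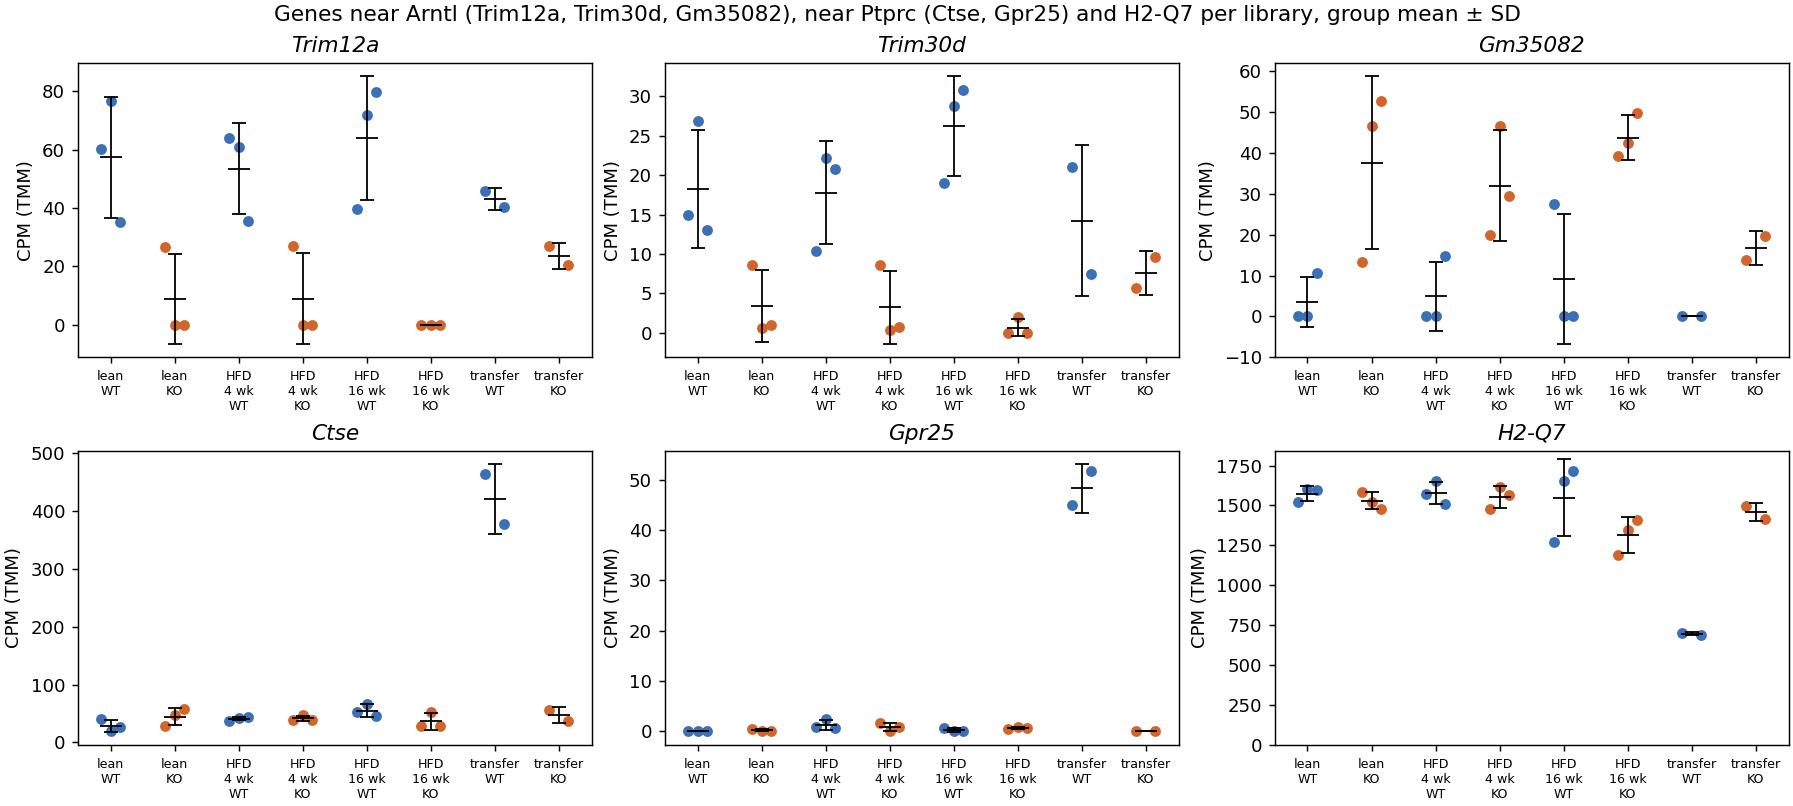
Genes near Arntl (Trim12a, Trim30d, Gm35082), near Ptprc (Ctse, Gpr25) and H2-Q7 in every library: the horizontal axis gives the 8 groups (WT blue, KO orange), the vertical axis TMM-scaled CPM, each point 1 library and the bars the group mean and SD. Trim12a is at 0 in 7 of 9 KO diet libraries, and the WT transfer group stands apart in Ctse (419.8 CPM), Gpr25 (48.4 CPM) and H2-Q7 (697 CPM).

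High fat diet for 4 weeks against lean diet, at the same age, left no gene past the threshold in WT. The smallest p values belonged to Cd5, a brake on T cell receptor signalling (log2 0.49), the adaptor Sh2d2a (0.47), the protease Tmprss13 (2.14), the splicing factor Sart1 (-0.79), the nucleoporin Nup43 (-1.09) and the tRNA synthetase Vars (-0.50), all with an adjusted p of 0.784. Sterol and fatty acid synthesis genes had 23 of 26 negative folds (median -0.33, camera adjusted p = 7.6e-07), with 1 that fell adjusted over the list alone. Interferon-stimulated genes had 24 of 25 positive folds (0.39, camera adjusted p = 1.17e-06) and heat shock genes 11 of 11 negative folds (median -0.30, camera adjusted p = 0.0215), with 0 adjusted over the list alone. Core Treg genes (0.21, camera adjusted p = 0.0215) and fatty acid oxidation genes (0.06, camera adjusted p = 0.0392) each had 2 that rose adjusted over the list alone. Oxidative phosphorylation genes (38 of 54 positive, 0.11, camera adjusted p = 0.00856) and B cell markers (4 of 4 positive, 0.75, camera adjusted p = 0.0427, summed 618 ± 191 against 443 ± 99.3 CPM) had 0. Summed macrophage markers were 130 ± 62.6 against 96.7 ± 30.5 CPM, dendritic cell and class II markers 146 ± 31.9 against 101 ± 12.3 CPM, and WT library 3 of 4 weeks had the highest macrophage (201 CPM) and B cell (832 CPM) sums of its group. Of these 7 lists 0 members passed over all genes. With an estimated correlation the adjusted p was 0.43 for the oxidative phosphorylation and heat shock lists and 0.304 for the other 5. edgeR called 0 genes, with 654 at an unadjusted p under 0.05, and DESeq2 called 0.

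In KO, 4 weeks of high fat diet also left no gene past the threshold. The smallest p belonged to Neat1, a nuclear long non-coding RNA, at 481 ± 33.997 CPM on high fat and 879 ± 98.4 CPM on lean diet (log2 -0.87, adjusted p = 0.109). The early response genes Jun (-1.22, adjusted p = 0.213), Fos (-1.08) and Cd69 (-0.79, adjusted p = 0.223) were among those that followed. Sterol genes had 25 of 26 negative folds, 8 of which fell adjusted over the list alone (median -0.43, camera adjusted p = 2.33e-09). Immediate early genes had 21 of 25, with 8 that fell and 1 that rose adjusted over the list alone (-0.40, 8.31e-08). Oxidative stress genes (19 of 24 negative, -0.14, camera adjusted p = 0.0284), oxidative phosphorylation genes (43 of 54 negative, -0.08, 0.00337) and heat shock genes (10 of 11 negative, -0.12, 0.0284) had 0 adjusted over the list alone. The adipose Treg signature (16 of 22 negative, -0.24, 0.0454) had 1 that fell. With an estimated correlation the adjusted p was 0.307 for the sterol, immediate early and oxidative stress lists and 0.696 for the other 3. Summed endothelial markers were 108 ± 16.9 against 61.5 ± 18.3 CPM on lean diet, and cytotoxic T and NK markers 139 ± 50.2 against 245 ± 63.9 CPM. edgeR called 0 genes, with 836 at an unadjusted p under 0.05, and DESeq2 called 13.

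After 16 weeks of high fat diet, in mice 30 rather than 18 weeks old so that diet and age are not separable, cholesterol synthesis genes fell in WT Tregs. Srebf2, the master regulator of sterol synthesis, fell from 339 ± 59.2 to 173.5 ± 5.36 CPM (log2 -0.96 ± 0.13, adjusted p = 0.00424). Crip1 (log2 -1.17 ± 0.17, adjusted p = 0.00424), the early factor Fosb (-1.31 ± 0.22, 0.0181) and the cytotoxic protease Gzmb (-2.27 ± 0.40, 0.0232) also fell. Pdcd1, encoding PD-1, rose from 347 ± 80.3 to 841 ± 171 CPM (1.27 ± 0.20, 0.00881). Tnfrsf9, an activation receptor, rose from 96.9 ± 20.7 to 271 ± 92.3 CPM (1.48 ± 0.26, 0.0213) and Ltb, a lymphotoxin chain, from 549.7 ± 69.5 to 907 ± 91.3 CPM (0.72 ± 0.12, 0.0181). Ahnak (-0.89, 0.0363), chosen after its value was seen, was also called.

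Of the 26 sterol genes 3 fell in WT at 16 weeks, or 20 adjusted over the list alone (median log2 fold change -0.89, camera adjusted p = 2.17e-24, adjusted p = 0.0234 with an estimated correlation). Of 25 immediate early genes 1 fell, or 4 with 1 that rose adjusted over the list alone (-0.24, camera adjusted p = 0.0152). Interferon-stimulated genes (22 of 25 positive, 0.45, camera adjusted p = 0.000219), cell cycle genes (23 of 27 negative, -0.35, 0.0152) and mitochondrially encoded genes (7 of 7 positive, 0.28, 0.0152) had 0 past the threshold, also adjusted over the list alone. For these last 4 lists the adjusted p was 0.676 with an estimated correlation. Summed B cell markers were 686.0 ± 283 CPM at 16 weeks and 443 ± 99.3 CPM on lean diet. The summed macrophage and endothelial markers at 16 weeks were 173 ± 74.0 and 95.4 ± 60.6 CPM, the latter 60.58 CPM without WT library 1, against 96.7 ± 30.5 and 75.2 ± 10.5 CPM on lean diet. edgeR called 3 genes higher and 7 lower. The count was 3 without lean WT library 1, 5 without lean WT library 3 or without WT library 1 or 3 of the 16 weeks group, and 28 without its WT library 2. Srebf2 and Crip1 kept their calls in all 6 leave-one-out fits. Tnfrsf9, Fosb, Ltb, Gzmb and Pdcd1 lost theirs in 2 to 4 of these fits, with adjusted p up to 0.246, 0.225, 0.219, 0.148 and 0.0533 in that order. In the fit of these 2 groups alone Srebf2 and Crip1 were at 0.0881 and 0.108, their highest over all alternatives.

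In KO, 276 genes were higher and 420 lower after 16 weeks of high fat diet than on lean diet. Whether this differs from WT is a test of the interaction, by which edgeR called 0 genes (993 at an unadjusted p under 0.05, and 26 by DESeq2). Sterol synthesis fell most broadly, with 17 of 26 genes that fell and 22 adjusted over the list alone (median log2 fold change -1.16, camera adjusted p = 1.57e-22, adjusted p = 0.0316 with an estimated correlation). Sqle, the squalene epoxidase gene, fell from 128 ± 9.58 to 27.976 ± 6.09 CPM (log2 -2.19 ± 0.26, adjusted p = 4.61e-05), and Hmgcs1 (-2.20), Cyp51 (-1.54) and Srebf2 (-1.10) fell with it. Immediate early genes fell too: 16 of 25 fell and 1 (Dusp4, 1.10) rose, or 19 and 2 adjusted over the list alone (median -1.08, camera adjusted p = 3e-16, adjusted p = 0.0451 with an estimated correlation). Egr1 went from 1443 ± 348 to 206 ± 46.5 CPM (-2.80 ± 0.27, 5.15e-06), Fos from 4175 ± 479 to 834 ± 87.1 CPM (-2.32), and Fosb from 385 ± 56.5 to 70.8 ± 24.9 CPM (-2.45). Cd69 (-1.69), Jun (-1.84) and Klf6 (-1.53) fell as well. Summed heat shock genes were 5504 ± 94.8 CPM in KO at 16 weeks and 6917 ± 1810 CPM in lean KO, where library 1 had 9005 CPM.

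The adipose tissue Treg signature, genes that set fat Tregs apart from lymphoid ones, had 13 of 22 members that fell and 2 that rose in KO at 16 weeks. Adjusted over the list alone these were 16 and 2 (median log2 fold change -1.12, camera adjusted p = 7.82e-09, adjusted p = 0.10 with an estimated correlation). The chemokine receptor Ccr2 fell from 851 ± 43.5 to 251 ± 38.1 CPM (log2 -1.76 ± 0.22, adjusted p = 7.13e-05). Klrg1, a marker of effector Tregs, also made by cytotoxic cells, fell from 1517 ± 4.55 to 447 ± 129 CPM (-1.76) and Irf4, a factor of effector Tregs, from 244 ± 38.7 to 96.3 ± 9.45 CPM (-1.34). Il9r (-1.85), Gm2a (-1.51) and Id2 (-1.07) also fell. Of the other members past the threshold, named after their values were seen, Pparg, the lineage regulator of fat Tregs (-2.26, adjusted p = 0.00471), Il10 (-1.96), the IL-33 receptor gene Il1rl1 (-1.25) and Gata3 (-0.73) fell. Nt5e (1.39) and the fatty acid transporter Cd36 (3.66) rose. Summed stromal, adipocyte and endothelial markers were 87.8 ± 127, 53.5 ± 33.1 and 179.9 ± 56.3 CPM at 16 weeks against 10.01 ± 4.36, 23.5 ± 1.87 and 61.5 ± 18.3 CPM on lean diet in KO. Without KO library 1 of 16 weeks the stromal and adipocyte means were 14.4 and 34.4 CPM, that library having 235 and 91.6 CPM. Cd36 is also abundant in those cells. Summed cytotoxic T and NK markers fell from 245 ± 63.9 to 132 ± 12.6 CPM and mesothelial and epithelial markers from 186 ± 38.7 to 112 ± 2.05 CPM.

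Interferon-stimulated genes rose in KO at 16 weeks, with 7 of 25 past the threshold and 10 adjusted over the list alone (median log2 fold change 0.77, camera adjusted p = 1.09e-07, adjusted p = 0.256 with an estimated correlation). Oas1a, an antiviral enzyme gene, rose from 14.3 ± 1.51 to 49.7 ± 10.7 CPM (log2 1.79 ± 0.39, adjusted p = 0.00881), and Rtp4 (2.06), Oas3 (1.40), Gbp2 (1.06) and Irgm1 (0.91) rose as well. Of the 4 B cell markers 1 rose over all genes and 4 adjusted over the list alone (median 1.91, camera adjusted p = 0.000942, adjusted p = 0.10 with an estimated correlation). Ighm went from 351.5 ± 18.0 to 982 ± 236 CPM (1.48, 0.00152), and the summed markers from 368 ± 11.4 to 1029 ± 265 CPM. Of 3 macrophage markers 1 rose (Ctss, 1.75; camera adjusted p = 0.118), their sum going from 77.9 ± 10.5 to 217 ± 54.4 CPM. Of 6 dendritic cell and class II markers 1 rose (Cd74, 2.11; camera adjusted p = 0.781), with a negative median (-0.39) beside a positive mean (0.04) and test. Cell cycle genes had 27 of 27 positive folds with 0 past the threshold either way (0.46, 0.000942, and adjusted p = 0.616 with an estimated correlation). Of 24 oxidative stress genes 2 fell (Glrx, -0.66, and Gpx1, -0.76), or 3 adjusted over the list alone (-0.19, 0.0484, and adjusted p = 0.256 with an estimated correlation). Of 14 resting and lymphoid tissue genes 3 rose, Tcf7 (1.69), S1pr1 (1.06) and Lef1 (0.80), or 3 with 1 that fell adjusted over the list alone (0.58, 0.0484, and adjusted p = 0.619 with an estimated correlation). Tcf7 lost its call without lean KO library 1 (adjusted p = 0.0508) and Lef1 in 5 of the 6 leave-one-out fits (up to 0.115). Leaving out 1 library also ended the calls of Rtp4 (without lean KO library 2, adjusted p = 0.0630), Gbp2, Irgm1, Oas3, Gpx1 and Glrx, the last in all 6 fits, with adjusted p up to 0.125. Both KO libraries 1 and 3 of the 16 weeks group did so for Gpx1, and lean KO library 2 did so for Rtp4, Gbp2, Irgm1 and Oas3.

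Among genes with the greatest folds in KO at 16 weeks, Bgn and Lad1 had 0 counts in the lean libraries and were at least 6.11-fold and 4.954-fold higher by 3 counts per library, and Rac3 had 0 counts at 16 weeks and was at least 4.964-fold lower. The Bgn bound rests on KO library 1 of 16 weeks (20.9 CPM) and is 1.63-fold without it. Cdcp1 (log2 5.44), Dnase1l3 (4.56), the endothelial Cldn5 (4.29) and the hypoxia factor Epas1 (3.93) rose, and Dyrk3 (-4.88), Plcg2 (-4.77), Rtn2 (-4.09), Acsl3 (-3.86) and Pacsin3 (-3.78) fell. Of the 276 genes that rose, 6 stand in the lists of other cells (Cd74, Cldn5, Ctss, Fabp4, Ighm and Pecam1), and of the 420 that fell, 0. Of the 24 listed markers tested these 6 are 25%, against 2.31% of the 11674 other genes. The count of 696 became 384 and 373 without KO library 1 or 3 of this diet, and 396 and 411 without lean KO library 1 or 2. Of 74 named genes that passed, 42 kept their call in all 6 leave-one-out fits, among them each sterol, immediate early and adipose Treg gene given CPM values here, with Oas1a and Ighm. The 32 others lost it in at least 1. Of 73 measured there, 21 lost it without KO library 1 of this diet, and of 74, 17 and 15 did without KO libraries 2 and 3. Without lean KO libraries 1, 2 and 3 the losses were 21, 22 and 13 of 74. Of the genes with the greatest folds, Rac3, Epas1 and Pacsin3 kept their call in all 6, Bgn and Lad1 lost it without each lean KO library (adjusted p up to 0.0774 and 0.0679), and Plcg2 lost it in 5 (up to 0.156). Cldn5, Rtn2 and Acsl3 lost it in 4, Dnase1l3 and Dyrk3 in 3 and Cdcp1 in 1, with adjusted p up to 0.144.

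**Figure D3:**
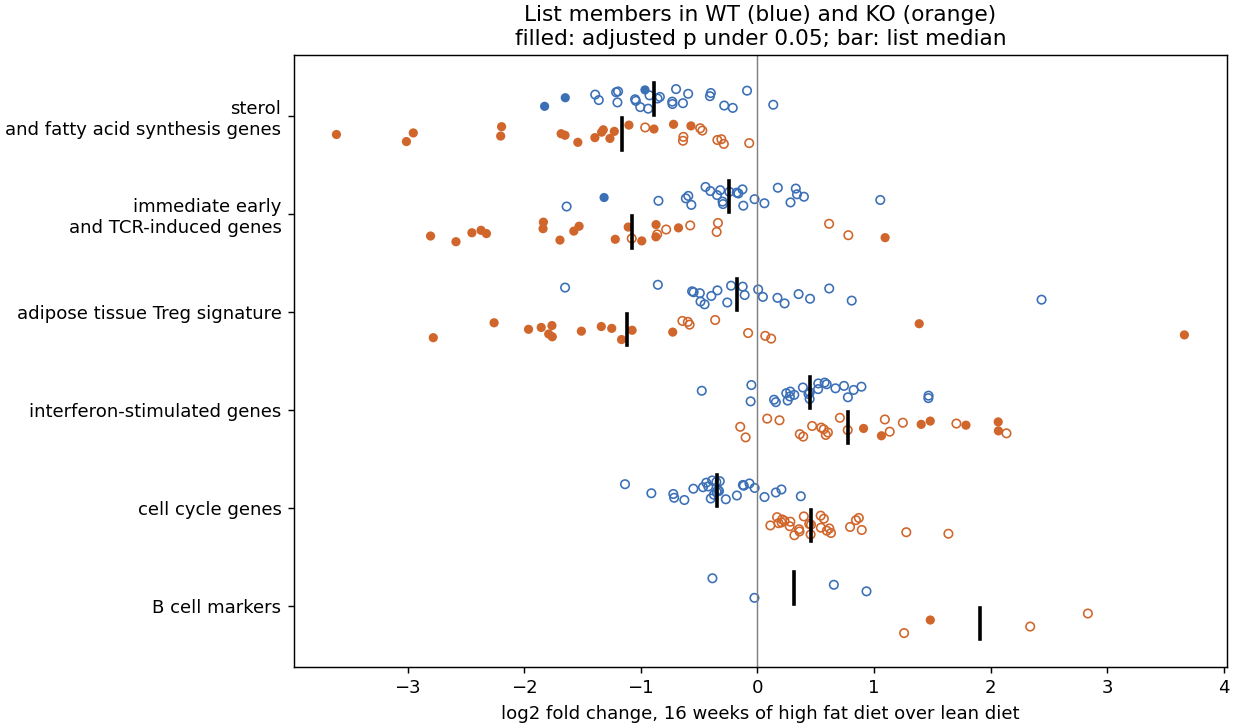
Members of 6 gene lists at 16 weeks of high fat diet: the horizontal axis is the log2 fold change over lean diet, each point 1 gene in WT (blue) or KO (orange), filled at an adjusted p under 0.05, and the bar the list median. The sterol list median is -0.89 in WT and -1.16 in KO, while the immediate early median is -0.24 in WT and -1.08 in KO.

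Both genotypes moved mostly the same way at 16 weeks. Of the 696 genes called in KO, 615 (88.4%) had a fold of the same sign in WT. Their median size on the log2 scale was 0.37 in WT and 1.13 in KO, the latter raised by the choice of genes called in KO. Of the 10 genes called in WT 9 were also called in KO, where independent lists would share 0.595. Across 7781 genes, which are not independent replicates, the folds had a Pearson correlation of 0.42 and a Spearman correlation of 0.32.

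**Figure D4:**
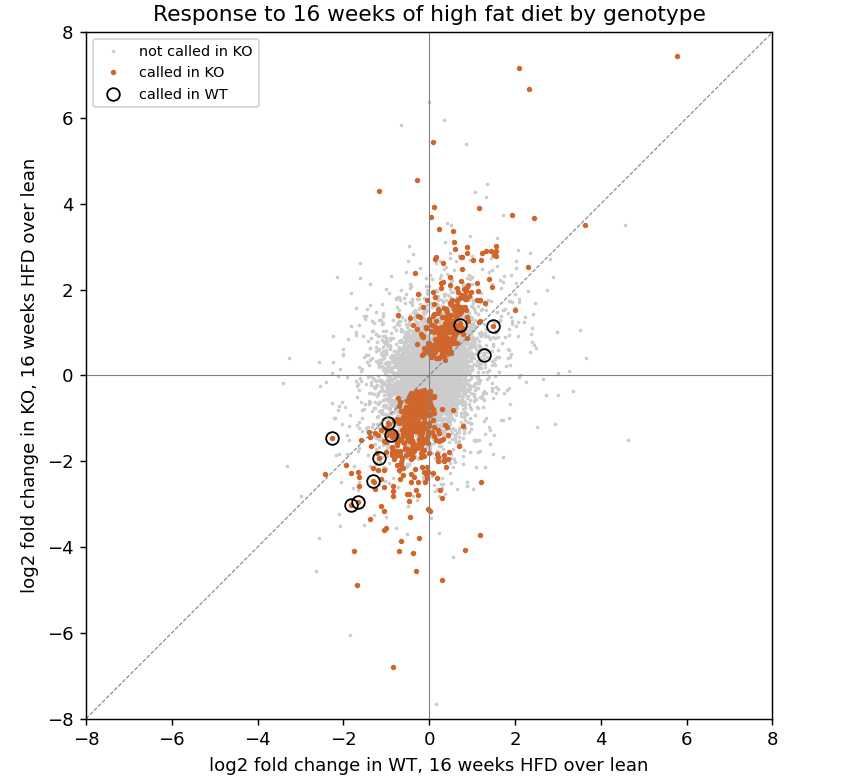
Log2 fold change after 16 weeks of high fat diet over lean diet, WT on the horizontal and KO on the vertical axis, each point 1 gene; orange points are called in KO, circles in WT, and the dashed line marks equal folds. Of the genes called in KO, 615 of 696 share the sign of their fold in WT, and most lie farther from 0 in KO.

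The interactions ask whether the KO effect itself differs between diets. At 16 weeks against lean diet the smallest p values belonged to the early response genes Egr1 (log2 -1.95), Fos (-1.71) and Jun (-1.67), to Ccr3 (-2.06), Zswim4 (-1.56) and Ttll12 (1.55), all with an adjusted p of 0.123, so none passed. Atp11b (1.36, adjusted p = 0.184), Dpp4 (1.86) and Nod1 (2.13, adjusted p = 0.242) followed. At 4 weeks Erbb3 (2.21), Nus1 (-1.37) and Sertad1 (-0.94) had the smallest p, all with an adjusted p of 0.912. edgeR called 0 genes for the interaction at 16 weeks, with 993 at an unadjusted p under 0.05, and DESeq2 called 26. At 4 weeks edgeR called 0, with 534 at an unadjusted p under 0.05, and DESeq2 called 0. Leaving out lean WT library 1 gave 15 calls at 16 weeks, and leaving out WT library 1 of the 16 weeks group gave 36.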

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

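The tests chosen only after their result was seen were those of BMAL1 loss for the genes near Arntl and near Ptprc and both tests of RNA from other cells. The other tests were chosen before their result was seen, but the windows near Arntl and Ptprc were set after the calls there were seen.

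Lists whose KO effect differed between diets by camera on the interaction are given first. At 4 weeks of high fat diet against lean diet the immediate early list had a median log2 difference of -0.31 (camera adjusted p = 5.78e-05, adjusted p = 0.448 with an estimated correlation, fry adjusted p = 0.436). The interferon-stimulated list was at -0.24 (camera 0.0321, adjusted p = 0.782 with an estimated correlation, fry 0.87) and the oxidative phosphorylation list at -0.15 (camera 1.1e-05, adjusted p = 0.448 with an estimated correlation, fry 0.414). At 16 weeks the immediate early list was at -0.92, with 18 of 25 genes that fell and 1 that rose adjusted over the list alone (camera 8.51e-14, adjusted p = 0.143 with an estimated correlation, fry 0.0224). The adipose Treg signature was at -0.75, with 10 of 22 that fell adjusted over the list alone (camera 2.5e-07, adjusted p = 0.302 with an estimated correlation, fry 0.124). Sterol synthesis was at -0.32, with 4 of 26 that fell adjusted over the list alone (camera 0.00172, adjusted p = 0.561 with an estimated correlation, fry 0.33). Cell cycle genes were at 0.77 (camera 2.5e-07, adjusted p = 0.561 with an estimated correlation, fry 0.33). Interferon-stimulated genes were at 0.50 (camera 0.0224, adjusted p = 0.68 with an estimated correlation, fry 0.552) and B cell markers at 1.34 (camera 0.0127, adjusted p = 0.302 with an estimated correlation, fry 0.188), with 0 members past the threshold adjusted over the list alone.

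Genes called between KO and WT in the average over the diets lay near Arntl. The calls were 7 of 274 tested genes within 20 Mb of it (2.55%), against 9 of 11407 elsewhere (0.0789%), clock list genes left out. This window was set after the calls were seen, so these shares describe the pattern and do not test it. Reads shared between the Trim copies are argued against as the whole cause for the Trim genes, since the summed CPM of 9 family members fell by 0.77 ± 0.11 on the log2 scale (141 ± 21.995 in KO, 241 ± 39.8 in WT) instead of staying level, while a part stays open for Trim34a (11.3 CPM in KO, 26.9 CPM in WT), whose copy Trim34b went the other way (8.36 and 1.80 CPM). Loss of BMAL1 does not account for all variation of the 7 genes, since they varied together between libraries of the same genotype and diet. Their deviations from the group mean had a mean Pearson correlation of 0.60 (Spearman 0.538, lowest 0.398 when any 2 of the 18 libraries were left out). The highest of 1000 random gene sets had 0.256 and the 14 genes called elsewhere had 0.0143. Correlations kept their sign, and of these 14 genes 10 were higher and 4 lower in KO. Opposite changes from a shared source would cancel in such a mean, so 0.0143 does not show that they varied apart. For the 7 genes it was 0.69995 in KO and 0.334 in WT libraries alone, the latter reached by 1 random set. The 4 Trim genes had a mean correlation of 0.518 with the 3 others, so the shared variation was not limited to Trim copies. Random sets were drawn from all genes, so regulation shared by neighbouring genes was not told apart. The shared variation by itself therefore does not decide whether loss of BMAL1 is the whole cause of the KO effect. A strain variant carried along with the edited Arntl allele may be the source and stays open: after transfer, other genes in the window had an unadjusted p under 0.05 at an odds ratio of 1.38 (95% interval 0.854 to 2.14, Fisher's exact p = 0.163). Trim12a and Gm35082, picked after their values were seen, also differed within a genotype. Gm35082 had counts in lean and 4 weeks WT library 3 and 16 weeks WT library 1 (10.6, 14.7 and 27.6 CPM). There Trim12a was 35.3, 35.5 and 39.8 CPM, against 60.1 to 79.9 CPM in the other WT diet libraries, which had no Gm35082 count. Whether this follows alleles of the region was not tested. KO library 1 of lean diet and of 4 weeks had Trim12a at 26.5 and 26.9 CPM, where the other KO diet libraries had 0. Nr1d1 (4.48 and 1.12 CPM) and Nr1d2 (2.61 and 0.75 CPM) were nearly lost in both. Trim30d, Trim5, Trim34a, Gm1966 and Gm4759 were also highest in them among KO diet libraries, but Art2b was not. Except for Art2b, these values argue against loss of BMAL1 as the whole cause for the called genes near Arntl. The labels give no genotype of the flanking region, and loss of BMAL1 as a part of the cause stays open as well.

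Genes called between KO and WT after transfer lay near Ptprc: 5 of 94 tested genes within 10 Mb (Btg2, Camsap2, Ctse, Gm26781 and Gpr25) against 15 of 11621 elsewhere, in a window set because these calls were seen and with Gm26781 overlapping Gpr25 and Camsap2. Loss of BMAL1 as the cause is argued against for the 3 of them that were measured in the diet libraries, where their median log2 fold change was -0.12 in the direction seen after transfer, against a median size of 2.97 after transfer. A candidate explanation is a strain variant between the transferred WT and KO cells, such as a marked CD45 allele in the WT cells: genes of the window that were not called had an unadjusted p under 0.05 more often than elsewhere (odds ratio 2.54, 95% interval 1.29 to 4.64, Fisher's exact p = 0.00402), against an odds ratio of 0.948 in the average over the diets. The labels name no such allele and give 1 strain for all mice, so this is a hypothesis found and tested on the same libraries, and the direct check would be variant calls in the reads, which were not analysed here.

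After 16 weeks of high fat diet against lean diet edgeR called 696 genes in KO and 10 in WT. For the genes that fell, RNA from other cells taking the place of Treg RNA is argued against, since it would lower all Treg genes alike. The 20 core Treg genes had a median log2 fold change of 0.31 (quartiles -0.13 and 1.06, Foxp3 0.01 ± 0.11). The 420 that fell had -1.14 (quartiles -1.69 and -0.73). This cannot see other cells held in lean KO libraries and lost at 16 weeks, a source that was not tested. Summed cytotoxic T and NK markers were 184 to 312 CPM in lean KO libraries and 122 to 146 CPM at 16 weeks. Mesothelial and epithelial sums were 142 to 214 and 109 to 113 CPM, while B cell, macrophage, class II, endothelial, stromal and adipocyte means rose. Gene length and GC bias is argued against by a correction after which 90.3% of the KO calls (624 of 691 with values) passed in the same direction. For the genes that rose, RNA from other cells cannot be told apart from a change in Tregs: 6 of the 24 listed markers of other cells that were tested rose (25%, against 2.31% of other genes, Fisher's exact p = 1.54e-05), and the lists hold few of the genes such cells express. A response that differs by genotype may account for the count: 993 genes had an unadjusted interaction p under 0.05, more than in each of the other relabellings of genotype within diets (highest 969), so that 1 of 100, the real one, reached it, while edgeR called 0 genes past the adjusted threshold. Diet and age are not separable here, and the day of handling is not given by the labels, so both stay open.

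Other splits of the same libraries were also tested. For the average over the diets, 21 genes were called and at most 5 in the other splits of 100 drawn from 4000. Thus 1 of 100, the real one, reached the count, which argues against grouping by chance at that level for this count. The calls include 7 genes near Arntl that varied together, so the count does not stand for 21 independent effects. By unadjusted p under 0.05, the real count of 865 was reached by 3 of the 100, the real one included (highest other 959). For the interactions 0 genes were called at 4 and at 16 weeks, a count that any split reaches (100 of 100 drawn from 200, highest others 17 and 12), so these splits decide nothing. The other comparisons of diet libraries allow 10 splits, too few for a share under 0.05, and the 2 against 2 transfer libraries were not split. Their real counts and highest others were 5 and 0 for KO against WT on lean diet, 8 and 2 at 4 weeks and 5 and 0 at 16 weeks, each count reached by 1 split. For 4 weeks of high fat diet they were 0 and 0 in WT and 0 and 1 in KO, reached by 10 splits each. For 16 weeks they were 10 and 15 in WT, reached by 2 splits, and 696 and 2 in KO, reached by 1. The split with 15 calls put lean libraries 1 and 3 with 16 weeks library 2.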

How the results depend on the processing

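The alternatives chosen only after the data were seen were leaving out 3 libraries with high markers of other cells and not counting calls near Arntl or Ptprc. RLE scaling and the stricter filter kept each count within 1.5 times. Without the filter 41746 diet and 29278 transfer genes were tested and more were called. These were 135, 75 and 428 for KO against WT on lean diet, at 4 and at 16 weeks, 273 in the average, and 102 after transfer. They were 40 and 178 for 4 and 16 weeks of high fat diet in WT, 112 and 1085 in KO, and 22 and 258 for the interactions at 4 and 16 weeks. The cause was not tested for the changes that follow. DESeq2 gave 24 on lean diet, 47 at 16 weeks, 38 in the average, 61 after transfer, 59 for 16 weeks in WT, 13 for 4 weeks in KO and 26 for the interaction at 16 weeks. Fits of only the 2 groups compared gave 10 on lean diet, 50 at 16 weeks, 1 for 16 weeks in WT and 15 for 4 weeks in KO. The robust fit gave 5 for KO against WT at 4 weeks, 6 for 16 weeks in WT and 1 for 4 weeks in KO. All 22 libraries in 1 fit gave 37 after transfer. Leaving out 3 libraries with high markers of other cells gave 3 for KO against WT at 4 weeks and 419 for 16 weeks in KO, 391 of them shared with the 696. WT library 1 of 16 weeks was kept, though its B cell, macrophage and endothelial sums were 965, 253 and 165 CPM. In WT library 3, which was left out, these were 695, 157 and 54.0 CPM, with a higher cytotoxic T and NK sum (687 against 162 CPM). Counting no calls near Arntl left 14 in the average. For the list tests, an estimated correlation called 9 and fry 17, against 57 by camera.

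With the replicate number as a replicate block, the counts were 4 on lean diet, 5 at 4 weeks and 5 at 16 weeks for KO against WT, 20 in the average, and 40 after transfer. They were 10 and 699 for 16 weeks of high fat diet in WT and KO, and 0 for 4 weeks in both and for both interactions. Camera with the block made 57 list calls. The check of replicate numbers gave no sign of pairing, but it cannot exclude pairing.

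In leave-one-out fits the counts ran from 4 to 11 on lean diet (11 without lean WT library 1), 4 to 6 at 4 weeks, 4 to 35 at 16 weeks (35 without WT library 1 of that group), 16 to 29 in the average and 15 to 21 after transfer. They ran from 0 to 0 for 4 weeks of high fat diet in WT and in KO, 3 to 28 for 16 weeks in WT (28 without WT library 2 of that group), 373 to 514 for 16 weeks in KO, 0 to 0 for the interaction at 4 weeks and 0 to 36 at 16 weeks. Of 3788 checks of named genes under the alternatives, 3433 kept direction and side of the threshold, 252 lost it, 103 gained it and 0 reversed, and 61 changed sign with neither value past it. Depth limits genes with few counts: the floor of 3 counts is 0.506 to 1.63 CPM in a library.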

Other observations

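No test in this part was chosen after its result was seen beyond those named before; the gene groups come from the lists fixed before the data were examined, and H2-Q6 and Gm35082 were chosen after their values were seen.

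Several lists without a call held genes that changed in opposite directions in KO after 16 weeks of high fat diet. Of 20 NF-kB targets 4 rose and 4 fell: the non-canonical subunits Nfkb2 (log2 0.58) and Relb (0.86) rose with Cd83 and Tnfrsf1b. The canonical subunit Nfkb1 (-0.84), the inhibitor Nfkbia (-0.96), and Nfkbiz (-0.93) and Nfkbid (-0.85) fell (camera adjusted p = 0.942, median -0.08, mean 0.05). Of 20 apoptosis and p53 targets 3 rose, including the death receptor Fas (1.37) and Bid, and 4 fell, the cell cycle inhibitor Cdkn1a (-1.42), Bcl2l1 (-0.81), Pmaip1 (-0.94) and Bax (-0.54; camera adjusted p = 0.77, median 0.03, mean -0.11). Of 20 core Treg genes 5 rose, including Nrp1 (1.09), Icos (0.87), Izumo1r (1.22), Ikzf4 (1.05) and Tnfrsf9, and 3 fell, Il2ra (-1.13), Socs2 (-1.05) and Capg (camera adjusted p = 0.083). Cd83, Tnfrsf1b, Bid, Tnfrsf9 and Capg were named after their values were seen. Without lean KO library 1 Relb lost its call (adjusted p = 0.0750). Nfkb2, Nfkbid, Pmaip1 and Bax lost theirs in 2 to 5 of the 6 leave-one-out fits, with adjusted p up to 0.121; KO library 1 of 16 weeks was among these for all but Pmaip1, which was lost without KO libraries 2 and 3 and lean KO library 1.

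In the same comparison of 11 T helper effector genes Lta rose (log2 2.86) and Il5 (-2.13) and Gzmb (-1.47) fell (camera adjusted p = 0.886). Metabolic lists each had 1 gene past the threshold: Ndufa4 (0.60) of the oxidative phosphorylation list (camera adjusted p = 0.249), Hif1a (0.97) of glycolysis (0.235) and Cpt1a (0.57) of fatty acid oxidation (0.329), and mitochondrially encoded genes had 0 (0.235). Herpud1 fell (-0.54) in the unfolded protein response list (0.0511), and 0 heat shock genes passed, with 4 that fell adjusted over the list alone (0.0511). Of the clock lists Bhlhe40 rose (1.52) and Per3 (-1.99) and Npas2 (-1.81) fell (camera adjusted p = 0.911 and 0.21; the BMAL1-CLOCK list had a median of 0.06 and a mean of -0.17). In leave-one-out fits Cpt1a lost its call in all 6, Il5, Gzmb, Ndufa4 and Per3 in 5 and Npas2 in 2, with adjusted p up to 0.152, and Herpud1 without KO library 1 of 16 weeks (0.0534). After transfer H2-Q6, a class I gene beside H2-Q7, was 998 CPM in KO and 598 ± 35.0 CPM in WT (log2 0.74, adjusted p = 0.0267), where the diet groups had 982 to 1215 CPM. Gm35082, a non-coding gene on chromosome 7, went against the Trim genes, with 43.8 ± 5.40 CPM in KO and 9.19 ± 15.9 CPM in WT at 16 weeks (27.6 CPM in WT library 1 and 0 in the other two) and 16.8 ± 4.16 CPM in KO and 0 in WT after transfer.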
